A study of Mus musculus with 7 samples.

How the data were processed

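Each library held the RNA of 1 neuron drawn into a patch pipette from an acute slice of mouse hippocampus. Per the labels, the cells came from the stratum oriens/alveus of area CA1 in mice that carry enhanced green fluorescent protein (eGFP) under control of the Vip gene. Vip encodes vasoactive intestinal polypeptide and marks a class of inhibitory interneurons. Cells had been recorded, filled with biocytin and kept when their axon was traced to the subiculum, the main output field next to CA1. Complementary DNA was made with the SMART-Seq v4 kit, which reads whole transcripts, keeps no strand and carries no molecular identifiers. Libraries were made with Nextera XT and sequenced as paired ends, per the labels' protocols.

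For every transcript, the deposited tables list an estimated count and a TPM value (transcripts per 1000000), per the file headers, beside a length and an effective length. The submitters' processing notes name STAR 2.5.2a, kallisto and the mm10 genome build. The role and settings of each tool, and the transcript annotation, are not given in the sources used here. The transcript identifiers showed that the tables were made on different indexes. Those of cells 1 to 5 list 107278 RefSeq transcripts, that of cell 6 lists 107277 and that of cell 7 lists 88197 Ensembl transcripts. The deposited TPM values were therefore normalised separately, and levels set side by side across cells carry that limit. The table of cell 7 has rows for mitochondrially encoded genes, which took 18.1% of its TPM. The tables of cells 1 to 6 have none, but list 7 short or noncoding entries, among them Bc1 and Gm41051, that took 27.7% to 81.6% of TPM.

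TPM and estimated counts were summed over the transcripts of a gene symbol. Symbols that a spreadsheet had turned into dates, or that were missing, were looked up by transcript accession. This repaired 122 of 157 symbols in each of cells 1 to 6 and 81 of 1210 in cell 7. Rows left without a gene name held at most 0.0362% of TPM in cells 1 to 6 and 0.482% in cell 7, and were left out. In total, 21414 genes were named in all 7 tables, of which 20637 were protein-coding and not mitochondrially encoded. Gene positions are from GENCODE M21, on the mm10 assembly.

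The labels put the 7 cells in 1 group and tie none of them to an animal. The group therefore counted as 1 sample, and no p-value or standard error was made from cells. The ranking of list spread and the rule for a cell far from the others do use the 7 cells as units, so they describe these cells alone. Values are given per cell, or as median and range, and an SD is the spread between the 7 cells. A gene was called detected above 1 TPM. Log values are log2(TPM + 1), a scale that understates differences between low values. A list level is the mean log2 value of its members. For a value of 0, the floor is the TPM that 3 counts would give for that gene and cell. Floors cover counting error only, since reads copied by PCR are not independent molecules. The libraries held 1052327 to 3398521 estimated counts.

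Each family of receptor or channel genes was described by the member with the highest TPM in each cell. Similarity between cells was the Spearman correlation across 7555 genes with a mean log2 value of at least 1. Such a correlation runs across genes, which are not independent replicates. The spread of a list was the median SD of its members, ranked among 10000 random lists of the same size matched on mean level (drawn from the 100 nearest genes). Lists needed 4 members with a mean log2 value of at least 1. On simulated data for this spread comparison (7555 genes), 20 of 20 lists given 2 times the SD ranked above the 95th percentile, as did 5 of 200 unchanged lists. The simulated genes varied independently, so the 5 of 200 may not hold for lists whose members vary together. A simulated list rise of 3 was recovered as 3.0, and a copied cell gave a correlation of 1.0. These outcomes were fixed in advance and check the arithmetic alone.

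The 33 gene lists covered interneuron classes, pan-neuronal and pyramidal genes, neuropeptides, calcium-binding proteins, receptors, channels, connexins, immediate early genes, nuclear-retained noncoding RNAs and other cell types of the slice. These lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named 18 genes of interneuron identity, up to 4 leading members of each list, the 10 genes with the highest mean log2 value and the 10 with the largest SD among genes with a mean of at least 5. Other list members named in the text, such as Tac2, Olig1 and Olig2, were chosen after their values were seen. Some genes that the rule names are not reported here. The alternatives fixed in advance were other detection thresholds, other pseudocounts, the highest transcript in place of the sum, removal of mitochondrial and ribosomal RNA genes, other filters and leaving out each cell. Rescaling TPM over the protein-coding genes shared by all tables, and detection by an estimated count of at least 5, were added after the indexes had been seen. The rescaling was also run without Rapgef4, Lars2 and Gm20594, because the origin of the reads on these abundant genes was in doubt. Leaving out each cell was added at the same point for the detection results. Calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots used matplotlib 3.10.9.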

Results

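The data described the transcripts of 7 long-range VIP neurons of mouse CA1, 1 library per cell. Such cells are inhibitory neurons whose axons leave the hippocampus proper, and the question addressed was which interneuron genes, receptors and channels they express. Total estimated counts were 1123136 in cell 1, 3398521 in cell 2, 1419828 in cell 3, 1052327 in cell 4, 2125424 in cell 5, 1110597 in cell 6 and 3225330 in cell 7. The median cell had 4481 genes above 1 TPM among those named in all tables. The range ran from 3095 genes in cell 7, the second deepest library, to 8174 in cell 2. The place of cell 7 depended on the threshold. Above 0 TPM it had 5686 genes, against 4739 in cell 1 and 5655 in cell 6. Of the protein-coding genes, 611 were above 1 TPM in all 7 cells and 3022 in a single cell. The 20637 shared protein-coding genes took 13.1% of TPM in cell 6 and 72.5% in cell 7, so a given TPM stood for different shares of messenger RNA.

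Vip was detected in 7 of 7 cells, at a median of 578 TPM. It reached 5006 TPM in cell 7 and 4299.6 in cell 2, and was lowest in cell 4 at 25.3 TPM, or 59 estimated counts. Rescaled over the shared protein-coding genes, Vip was higher in cell 2 (7370 TPM) than in cell 7 (6907). Gad1, which encodes an enzyme that makes GABA, was also detected in 7 of 7 cells, from 9.59 TPM in cell 6 to 490 TPM in cell 1. The companion enzyme gene Gad2 lay between 21.3 and 162 TPM in cells 1 to 6 and at 0.218 TPM (4 counts) in cell 7. Slc32a1, the vesicular GABA transporter, was at 6.48 to 14.8 TPM in cells 1 to 5 and listed at 0 in cells 6 and 7, where 3 counts would give 0.321 and 0.355 TPM. The interneuron transcription factor gene Dlx5 was above 1 TPM in cells 2 to 6, with 128 TPM in cell 4. A median of 7 of the 10 GABAergic core genes was detected per cell, with a range of 5 to 9. On the mm10 assembly, Vip lies on chromosome 10 (5639218 to 5647617, plus strand), Gad1 on chromosome 2 (70553072 to 70602014, plus strand) and Gad2 on chromosome 2 (22622205 to 22693874, plus strand).

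**Figure D1:**
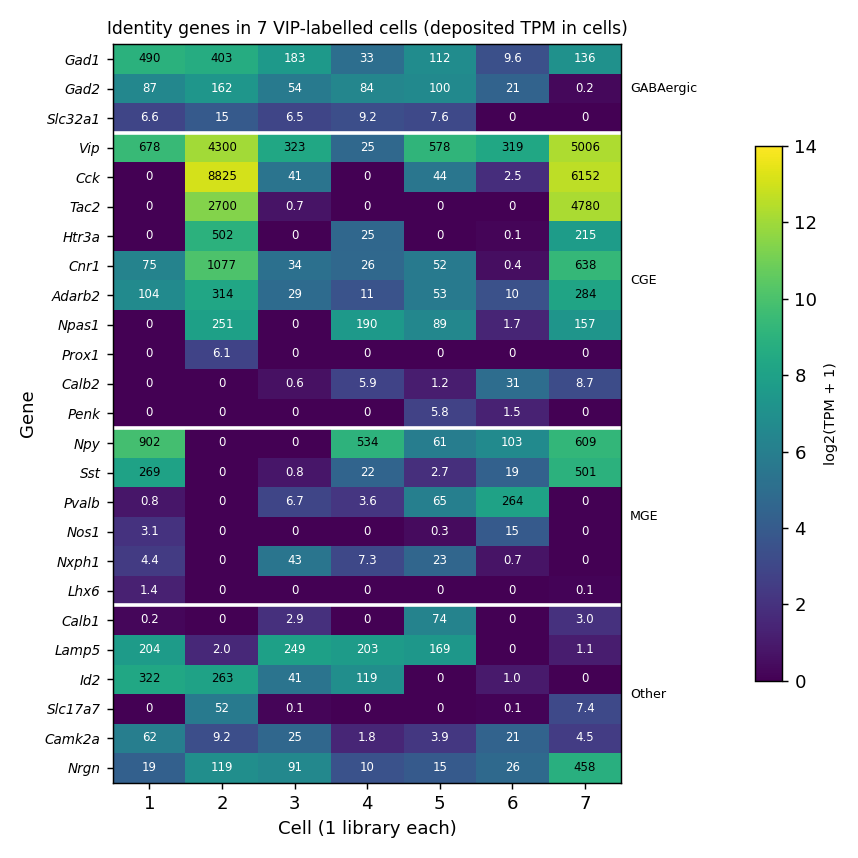
Deposited TPM of interneuron and pyramidal neuron genes (rows) in each of the 7 cells (columns), with colour for log2(TPM + 1) and the TPM printed in each square; tables were normalised separately. Vip was at 25.3 TPM or more in every cell, while Cck ranged from 0 to 8825 TPM.

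The GABAergic core list lay above the pyramidal neuron list in each of the 7 cells. The difference in mean log2(TPM + 1) averaged 2.32 ± 1.11 (SD, n = 7 cells) and ran from 0.51 in cell 7 to 3.58 in cell 5. Among the pyramidal genes, Camk2a and Nrgn, which encode synaptic signalling proteins, were detected in 7 of 7 cells, and Nrgn reached 458 TPM in cell 7. Slc17a7, the vesicular glutamate transporter of cortical pyramidal cells, was above 1 TPM in cell 2 (52.2 TPM) and cell 7 (7.38 TPM). Neurod1, Tbr1, Emx1 and Fibcd1 were above 1 TPM in no cell. The pan-neuronal list was detected more evenly, with a median of 10 of 11 genes. Snap25, Syt1, Rbfox3, Map2, Stmn2 and Uchl1 were above 1 TPM in 7 of 7 cells, and Snap25, a part of the vesicle fusion machinery, lay between 194 and 844 TPM. With only members above 1 TPM in at least 1 cell in both lists, the GABAergic list was above the pyramidal list in 6 of 7 cells.

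Genes of interneurons born in the caudal ganglionic eminence, the origin of VIP cells, were present in every cell but at very different levels. Vip and the RNA-editing family gene Adarb2 were the members above 1 TPM in 7 of 7 cells, and Adarb2 ran from 10.1 to 314 TPM. Cck, which encodes cholecystokinin, was at 8825 TPM in cell 2 and 6152 TPM in cell 7, but at 40.9 and 44.2 TPM in cells 3 and 5 and 2.54 TPM in cell 6. It was listed at 0 in cells 1 and 4, where 3 counts would give 2.78 and 3.03 TPM. Cnr1, the cannabinoid receptor gene, was likewise highest in cells 2 (1077 TPM) and 7 (638 TPM). Htr3a, a serotonin-gated channel subunit, was above 1 TPM in cells 2 (502 TPM), 7 (215 TPM) and 4 (24.9 TPM). Prox1, a transcription factor gene of this lineage, was detected in cell 2 alone, at 6.06 TPM. Calb2, which encodes calretinin, was above 1 TPM in 4 cells, with 31.1 TPM in cell 6. Penk, the enkephalin precursor gene, was at 5.77 TPM in cell 5 and 1.54 TPM in cell 6.

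Markers of interneurons from the medial ganglionic eminence were found next to Vip in several libraries. Transcripts typical of glia and blood were present in each library too. Expression by the recorded cell and RNA from neighbouring interneurons could therefore not be told apart. Npy was above 1 TPM in 5 cells, at 902 TPM in cell 1, 609 in cell 7 and 534 in cell 4. Rescaled over the shared protein-coding genes, it was at 2476 in cell 1, 1646 in cell 4, 840 in cell 7 and 785 in cell 6. Sst, the somatostatin gene, was at 501 TPM in cell 7 and 269 TPM in cell 1. Pvalb, the parvalbumin gene, was at 264 TPM in cell 6 and 64.8 TPM in cell 5. Lhx6, a transcription factor gene of this lineage, was above 1 TPM in cell 1 alone (1.43 TPM), and Nos1 in cells 1 and 6 (3.09 and 14.6 TPM). Chodl was above 1 TPM in no cell. The caudal list minus the medial list averaged 1.28 ± 2.31 (SD, n = 7 cells) and was positive in 4 of 7 cells, so the mean difference was smaller than the spread. It was 5.17 in cell 2 and 3.74 in cell 7, and lay between -1.24 and 0.81 in the other cells. Without cell 2 the mean was 0.63. Of the neurogliaform genes, Lamp5 was at 169 to 249 TPM in cells 1, 3, 4 and 5 and at 0 to 2.01 TPM in cells 2, 6 and 7. Id2 was above 1 TPM in cells 1 to 4, with 322 TPM in cell 1, and Reln was above 1 TPM in no cell.

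Neuropeptide precursor genes differed widely between the cells. Vip was the member of the 19-gene list above 1 TPM in every cell, and a median of 8 members was detected. Chga, a chromogranin of dense-core vesicles, was highest in cells 2 (565 TPM) and 7 (420 TPM). Pdyn, Gal, Grp and Nts were above 1 TPM in no cell. Of the calcium-binding proteins, the calmodulin genes Calm2 and Calm3 and the gene Vsnl1 were detected in 7 of 7 cells, and Calm2 was at 318 to 2840.2 TPM. Calb1, the calbindin gene, was at 74.4 TPM in cell 5 and at no more than 3.04 TPM elsewhere.

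Chrm2, the M2 muscarinic acetylcholine receptor gene, was the highest muscarinic gene in 4 of 7 cells. It was at 268 TPM in cell 4, 191 TPM in cell 5, 8.41 TPM in cell 1 and 7.23 TPM in cell 3, and below 1 TPM in cells 2, 6 and 7. Chrm1 led in cell 2 at 19.4 TPM and Chrm3 in cell 6 at 6.82 TPM, while Chrm4 and Chrm5 were above 1 TPM in no cell. Chrm2 lies on chromosome 6 (36388084 to 36528414, plus strand) on mm10. Nicotinic receptor genes were sparse, with a median of 1 of 9 members per cell. Chrnb4 was at 97.6 TPM and Chrna3 at 24.6 TPM in cell 2, Chrna4 was at 11.1 TPM in cell 4, and Chrna7 was above 1 TPM in no cell.

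Of 49 receptor genes for monoamines and peptides, 26 were above 1 TPM in 1 to 3 cells, 22 in no cell and 1 in 4 or more. The share in no cell was near that of all 20637 shared protein-coding genes, of which 9219 were above 1 TPM in no cell. The share in 4 or more cells was smaller than among those 20637 genes. Of them, 1536 were above 1 TPM in 4 cells, 1050 in 5, 735 in 6 and 611 in 7. Htr3a was the leading serotonin receptor gene in 3 cells, Htr6 was at 41.4 TPM in cell 2 and Htr7 at 8.78 TPM in cell 4. Adrb1, the beta-1 adrenergic receptor gene, was at 179 TPM in cell 1, 27.0 TPM in cell 4 and 10.4 TPM in cell 5. Drd1 was above 1 TPM in 3 cells with at most 9.85 TPM, and Drd2 was at 21.9 TPM in cell 4. Oprd1, the delta opioid receptor gene, was above 1 TPM in cells 3, 5 and 6 (12.6, 6.77 and 3.24 TPM). Oprm1, the mu opioid receptor gene, was listed at 0 in 7 of 7 cells, where 3 counts would give 0.480 to 1.01 TPM. Among other peptide receptors, Sstr2 was at 433 TPM in cell 7 and 92.1 TPM in cell 2, Npy1r at 133 TPM in cell 2 and Oxtr at 27.8 TPM in cell 5. The VIP receptor genes Vipr1 and Vipr2 and the cholecystokinin receptor genes Cckar and Cckbr were above 1 TPM in no cell.

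Ionotropic glutamate receptor genes were detected in each cell. Gria1 and Gria2, subunits of AMPA receptors, were above 1 TPM in 7 of 7 cells, and Gria2 was the highest AMPA subunit in 5 of them, with 689 TPM in cell 2. Grin2b was the NMDA receptor subunit detected in 7 of 7 cells, from 5.33 to 119 TPM, and Grin1 led in 4 cells. Grik1, a kainate receptor subunit, led in cells 3 (52.0 TPM), 4 (108 TPM) and 5 (117 TPM). Of the metabotropic receptors, Grm5 led in 4 cells, and Grm2, Grm6, Grm7 and Grm8 were above 1 TPM in no cell. Among the GABA-A subunits, Gabra2 was at 236 TPM in cell 2 and Gabrb1 at 178 TPM in cell 7. Gabbr1, a GABA-B receptor subunit, was above Gabbr2 in 7 of 7 cells and lay between 3.06 and 112 TPM.

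**Figure D2:**
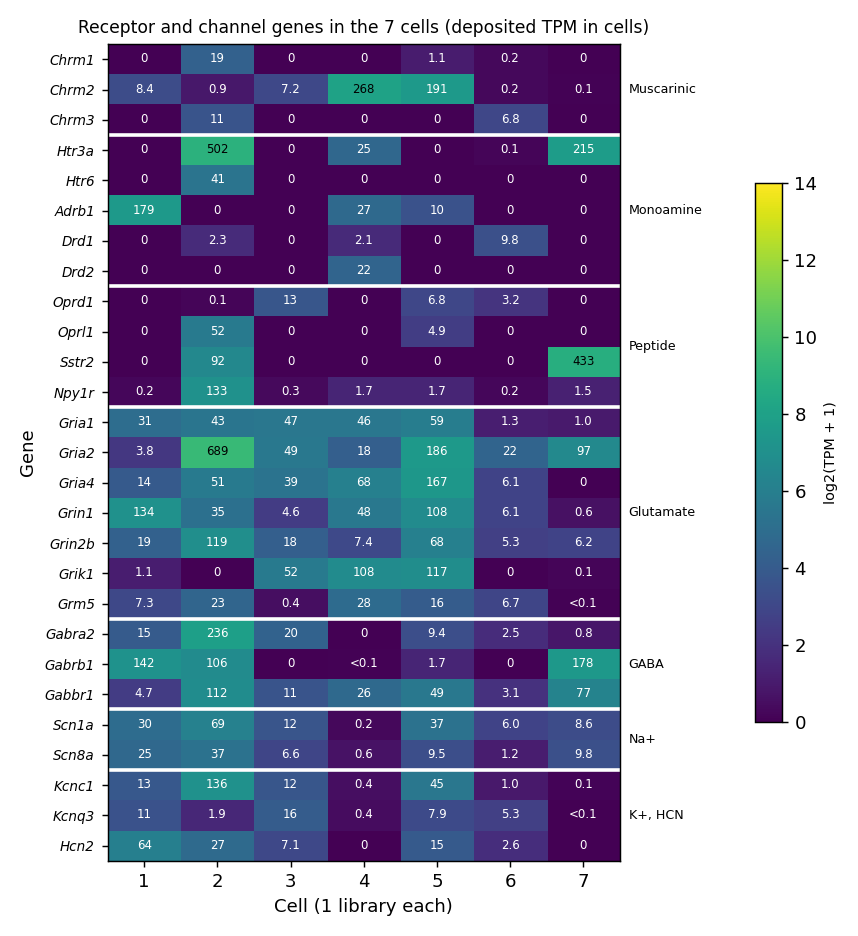
Deposited TPM of selected receptor and channel genes (rows) in each of the 7 cells (columns), with colour for log2(TPM + 1) and the TPM printed in each square; tables were normalised separately. Chrm2 was highest in cells 4 and 5, at 268 and 191 TPM, and Gria2 was detected in 7 of 7 cells.

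Among voltage-gated channels, sodium channel genes were detected at a median of 6 of 9 members per cell. Scn1a was at 69.0 TPM in cell 2 and 0.219 TPM in cell 4. Potassium channel genes had a median of 4 of 14 members, with Kcnc1 at 136 TPM in cell 2 and 45.4 TPM in cell 5. Of the HCN channels, Hcn2 was at 64.3 TPM in cell 1, and no member was above 1 TPM in cell 4. Calcium channel genes had a median of 2 of 8 members, with Cacna1b at 40.9 TPM in cell 2 and Cacna1g at 21.2 TPM in cell 3. Over the 17 families, 36 of 136 genes were above 1 TPM in 4 or more cells, a larger share than among all shared protein-coding genes. The number of family genes was 65 at a threshold of 0 TPM and 10 at a threshold of 10 TPM.

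Transcripts typical of glia and blood were present in each of the 7 libraries. Mbp, which encodes a myelin protein, was detected in 7 of 7 cells and ran from 62.2 TPM in cell 3 to 16129 TPM in cell 7. The astrocyte list included S100b and Aldoc in 7 of 7 cells and Sox9 at 89.1 TPM in cell 1, while Gfap and Aqp4 were above 1 TPM in no cell. Microglial genes varied widely. The complement gene C1qa was at 403 TPM in cell 3 and below 1 TPM in cells 6 and 7, and Aif1 was at 930 TPM in cell 7. The haemoglobin gene Hba-a1 was detected in 7 of 7 cells, at 54.2 TPM in cell 1 and 6765 TPM in cell 2. Of 8 vascular genes, Rgs5 was above 1 TPM in 4 cells and Pecam1 in cell 7, and the other 6 in none. A median of 16 of 41 markers of these other cell types was detected per cell. In cell 7, high Cck and Vip thus stood beside the highest oligodendrocyte level (5.42 on the log2 scale), and in cell 2 beside the highest red blood cell level (9.51).

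**Figure D3:**
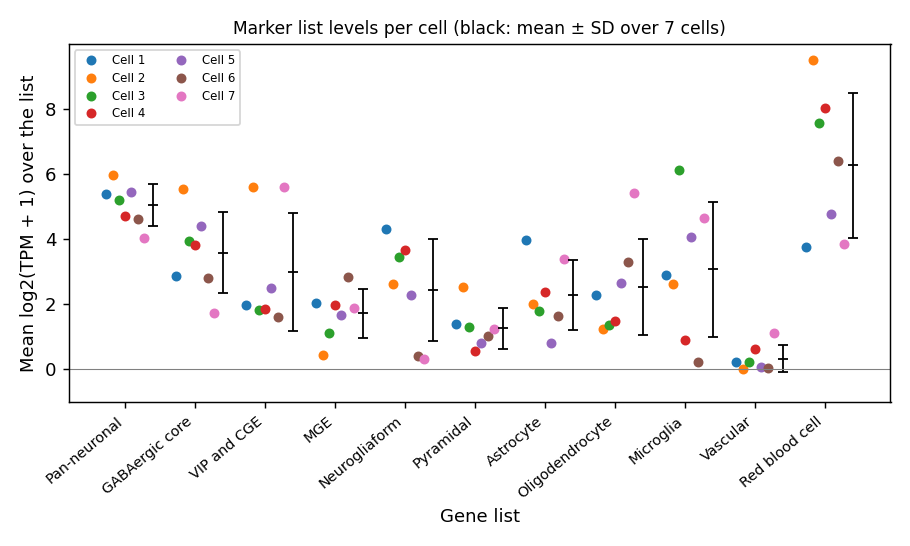
Mean log2(TPM + 1) of each marker list in each of the 7 cells (coloured points), with the mean and SD over cells in black. The pan-neuronal list lay between 4.04 and 5.97 in every cell, while the microglia list ran from 0.22 to 6.11.

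The median Spearman correlation across genes was 0.244 over 21 pairs of cells, with a range of 0.118 to 0.327. Cell 7, whose table alone lists Ensembl transcripts, had the lowest median correlation with the others (0.180, against 0.224 to 0.271). Without cell 7 the median over pairs was 0.253. The part of the index and that of the cell could not be told apart. Over the 618 genes above 1 TPM in every cell the median over 21 pairs was 0.599, and no pair came near identity. Of 18 lists ranked by spread, 4 lay above the 95th percentile of matched random lists, where chance gives 0.9 if members vary independently. They were the microglia genes (100th percentile), neuropeptides (99.3), VIP and caudal markers (98.8) and oligodendrocyte genes (96.8), and the neuropeptide and caudal lists share Vip, Cck, Tac2, Crh and Penk. The caudal list was at 54.6 on the shared protein-coding scale, 80.4 with a pseudocount of 0.1 and 94.3 without cell 6. Neuropeptides were at 92.7 with a pseudocount of 0.1, 89.0 without cell 2, 94.99 without cell 5 and 88.2 without cell 6, and oligodendrocyte genes at 86.1 without cell 7. Below the 5th percentile lay the sodium channels (0.41), pan-neuronal genes (0.73) and calcium channels (0.81). The pan-neuronal list was at 21.2 with a pseudocount of 0.1, 5.53 without cell 2 and 7.46 without cell 7. The calcium channels were at 24.1 with a pseudocount of 10, 19.1 without cell 3 and 8.88 without cell 5.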

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

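The technical tests weighed in this part were chosen after the values they concern had been seen. A value was picked out when 1 cell lay far from the other 6 relative to the whole range, on the log2 scale. This held for 31 of 183 values tested. Chance alone picks out about 1 in 20 normally spread values, and genes at or near 0 in most cells are picked out easily, as 17 of the 144 genes tested were at or below 1 TPM in 6 of 7 cells.

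Cell 2, the library with the most counts and the most genes above 1 TPM, stood above the others for several receptor genes. They were Chrnb4 (97.6 TPM), Chrna3 (24.6), Chrm1 (19.4), Htr6 (41.4), Oprk1 (18.5) and Npy1r (133). The transcription factor gene Prox1 (6.06 TPM) and the neuronal connexin gene Gjd2 (37.6) were also high there. So were the pyramidal list, at 2.53 on the log2 scale, and the serotonin receptor list, at 1.48. Cell 3 was high for Adra1a (5.13 TPM), Adrb3 (1.72), Grm4 (11.0), Hcn4 (7.07) and Cacna1g (21.2). Cell 5 was high for Calb1 (74.4 TPM), Oxtr (27.8) and Grm3 (7.66). Cell 4 was high for Htr7 (8.78 TPM), Drd2 (21.9) and Gjb6 (201), and cell 1 for Lhx6 (1.43) and the astrocytic connexin gene Gja1 (618). Cell 6 was low for Uchl1 (131 TPM), Cst3 (69.9) and Ppia (835). Cell 7 was low for Gad2 (0.218 TPM), Lars2 (204) and Rapgef4 (0), and high for the endothelial gene Pecam1 (83.7). The eGFP reporter, used in none of the comparisons, had 92, 117, 25, 178 and 475 estimated counts in cells 1 to 5, above the 3 counts that a count of 0 allows. The tables of cells 6 and 7 have no row for it, so the reporter was not measured there. The rule for a cell far from the others was then applied to the values rescaled over the shared protein-coding genes, a check added after these cells had been picked out, and 22 of the 31 still held. Where all other cells were at 0, as for Prox1, Chrna3, Htr6, Htr7, Drd2, Gjb6 and Pecam1, rescaling could not change the outcome. Those that no longer held were Chrnb4, Gjd2, the pyramidal list and the serotonin receptor list in cell 2, Calb1 in cell 5, Lars2 in cell 7, and Uchl1, Cst3 and Ppia in cell 6. After rescaling, cell 6 was still the lowest for Cst3 (534 TPM) but not for Uchl1 (1002 TPM, with 656 in the lowest cell) or Ppia (6375 TPM, with 3453 in the lowest cell).

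Rapgef4, a signalling gene, stood at 3473 to 14013 TPM in cells 1 to 6 and at 0 in cell 7. A difference in scale between the tables was argued against. At the lowest share of protein-coding counts found in cells 1 to 6 (1.08%), cell 7 would have held 28319 counts and it held 0. This replaced a test on rescaled TPM whose outcome was fixed in advance. The outcome of the replacement was all but fixed too, by a 0 in a library of 3225330 counts. It shows only that a change of scale cannot give the 0. Reads placed on a segment that 1 RefSeq transcript has alone may be the source, since at least 98.1% of the counts lay on 1 of 8 listed transcripts. The test could not decide, because 13 genes with at least as many transcripts were compared in cell 1 and 3 in cell 6, and a rule needing at least 20 was added after the value was seen. Without that rule the outcome turned on the reading of the 95th percentile in cell 1, where the share ranked at the 92.3 percentile but lay above the interpolated bound (99.999% against 99.918%).

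Myelin genes were highest in cell 7, with Mbp at 16129 TPM, Mobp at 1616 and Cnp at 756. Scale was argued against here too, because rescaled Mbp in cell 7 was 8.50 times the next highest cell. RNA from neighbouring oligodendrocytes may contribute, and 6 of 10 further oligodendrocyte genes were highest in cell 7, among them Qdpr (1359 TPM) and Cryab (747). At least 7 had been set as the number needed, and Cldn11 was at 0 in all cells while Trf was at 0.487 TPM in cell 7, so this stayed undecided. An earlier form of the test, on the myelin genes themselves, was dropped because those genes define the pattern.

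Cck, Tac2 and Vip were highest in cells 2 and 7. A test of carry-over between these libraries did not decide, as 78% of 50 abundant genes of cell 2 reached at least 0.5 times the level in cell 7 that carry-over would bring (36% from cell 7 to cell 2). The bounds of 90% and 50% were set after the pattern was seen. An earlier test on the SD of the ratio was dropped because the choice of genes all but fixed its outcome. Other rescaled values argued against carry-over as the source of these levels. It would need a ratio of at least 0.561 from cell 2 to cell 7, but Gad2 was at 277 and 0.301 TPM and Dlx5 at 144 and 0. From cell 7 to cell 2 it would need 0.702, but Npy was at 840 and 0 TPM and Sst at 691 and 0. Lower depth elsewhere was argued against, since 3 counts of Cck or Tac2 in the other cells were worth at most 0.106% of the lower of the 2 levels. RNA from a neighbouring Cck neuron without Vip may be involved and was not ruled out, as its test could hardly decide. High Vip in cells 2 and 7 is part of the pattern. The outcome set for this explanation, Vip not above the other 5 cells, was therefore all but excluded. Rescaled Vip in the lower of the 2 cells was 2.84 times the highest other cell. The bound for arguing against this explanation was the 31.2-fold range of the other 5 on the same scale. No biological explanation was tested for these patterns, as the design has 1 group.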

How the results depend on the processing

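The rescaling over shared protein-coding genes, detection by estimated counts, and leaving out cells for the detection results were chosen after the data were seen, and the other alternatives were planned. Of 117 values for the main results under alternatives, 106 stayed within the spread between cells or within 1.5 times the count, and 11 moved. This rule is loose, since the spread of the caudal minus medial difference (2.31) exceeded its mean (1.28). Counts cannot change sign, and none of the list differences or correlations did. The median number of other cell type markers was 25 at a threshold of 0 TPM, 11 at 10 TPM and 21 on the rescaled values, with or without Rapgef4, Lars2 and Gm20594. Receptor and channel genes above the threshold in 4 or more cells numbered 65 at 0 TPM, 20 at 5 TPM and 10 at 10 TPM. These shifts follow from the thresholds and the scale. The GABAergic minus pyramidal difference was 1.15 with a pseudocount of 10, which compresses low values by construction, and was positive in 7 of 7 cells. The median correlation between cells was 0.341 over genes above 0 in any cell and 0.599 over genes above 1 TPM in every cell. The cause was not tested. Lists of high spread numbered 2 to 5 when each cell was left out, and 2 without cell 6. The caudal minus medial difference ranged from 0.63 to 1.77 over its alternatives, lowest without cell 2. Among single genes and lists, 345 values stayed and 31 moved. Depth limits genes near 1 TPM, where a few counts can decide detection, but the counts behind 1 TPM differed by gene and cell. Calb2 was detected in cell 5 at 1.20 TPM on 4 counts. Nxph1 was not detected in cell 6, at 0.695 TPM on 35.0 counts.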

Other observations

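Immediate early genes, which neurons switch on within minutes of activity, were detected in each cell, at a median of 5 of 13. Junb was above 1 TPM in 7 of 7 cells and reached 285 TPM in cell 7. Fos was at 24.3 to 230 TPM in cells 1 to 6 and at 0.640 TPM in cell 7, and Egr1 was at 6.19 to 197 TPM in cells 1 to 6 and listed at 0 in cell 7. Npas4, Fosl2 and Btg2 were above 1 TPM in no cell. Nuclear-retained noncoding RNAs differed widely among cells 1 to 6, where Malat1 ran from 231 TPM in cell 6 to 20942 TPM in cell 2 and Meg3 from 54.0 to 2915 TPM. Snhg11, the member listed in all 7 tables, was between 39.0 and 3002 TPM. No connexin gene was above 1 TPM in more than 2 cells, and Gjc1 was above 1 TPM in none.

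The genes with the highest mean level over the 7 cells were Tmsb4x, Gm20594, Fth1, Cst3, Lars2, Ppia, Usmg5, Rapgef4, Cox8a and Ftl1. Whether the reads counted for Lars2 and Gm20594 came from those genes or from another RNA was not tested, and the test for Rapgef4 did not decide, so these 3 levels are not to be read as expression of the named genes. Tmsb4x, an actin-binding peptide gene, was at 828 to 7871 TPM, and Fth1, a ferritin subunit gene, at 550 to 15779 TPM. The largest SD on the log2 scale among well-expressed genes was that of Cck (5.51), followed by Rapgef4 (4.76), Gstm1 (4.23) and Npy (4.22). Krtcap2, Tyrobp, Rpl36al, Bola2, Psmc5 and Psenen completed the 10, and each of these 6 was at or near 0 in at least 1 cell. Tyrobp, a signalling adaptor of microglia, was at 1029 TPM in cell 5 and listed at 0 in cells 6 and 7. The transcription factor genes of the oligodendrocyte lineage were highest in another cell than the myelin genes, with Olig1 at 119 TPM and Olig2 at 90.6 TPM in cell 6. Spike-in control sequences totalled 7.89 to 25 estimated counts in cells 1 to 6.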
